A study of Homo sapiens with 12 samples.

How the data were processed

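RNA was measured in 12 libraries of MDA-MB-231 cells, 3 each of DMSO, CAR (10 µmol/L), JQ1 (25 µmol/L) and Combination. Per the labels' protocols, total RNA was isolated with RNAiso Plus, samples with an integrity number of at least 7 went on, and libraries were made with a stranded mRNA kit, which selects poly(A) RNA. The authors deposited 1 table per library with whole-number read counts per gene symbol, not normalized. The submitters' processing notes name Trimmomatic, HISAT2, HTSeq and the build hg38, without versions, roles or settings. The gene annotation and whether counting used strand are not given in the sources used here, so the reads of a gene and its antisense partner cannot be told apart. Reads of near-identical genes, such as histone copies or HSPA1A and HSPA1B, may be split or dropped by the counting. Every symbol listed had at least 1 count in at least 1 library, and no mitochondrially encoded gene and no summary line was listed. No time of treatment is given in the labels. Groups and replicate numbers came from the sample titles, except that the titles call the control CON and its treatment label gives DMSO, the name used here. Nothing says what the replicate numbers mark or that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

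Total counts ran from 17449715 to 19754456 per library, and 3 counts, taken as the floor, corresponded to 0.152 to 0.172 CPM. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Counting intervals are exact at the 95% level. The length trend of a library is the Spearman correlation across genes of at least 5 log2 CPM between transcript length and the deviation from the mean of the other libraries of its group. The chi-square between replicates used genes with a summed count of at least 20. No pair of replicates agreed within sampling noise.

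The counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group (minimum count 10, minimum total 15) were kept, 12645 of 16384, and libraries were scaled with TMM factors, which ran from 0.921 to 1.08. A quasi-likelihood model with robust estimation was fitted to all 12 libraries with 1 coefficient per group, which left 8 residual degrees of freedom and a common biological coefficient of variation of 0.0408. The 6 contrasts were CAR minus DMSO, JQ1 minus DMSO, Combination minus DMSO, Combination minus JQ1, Combination minus CAR, and the interaction (Combination minus CAR minus JQ1 plus DMSO). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. The log2 CPM of the principal components used a prior count of 2. A fold below 1 is given as its inverse, with the direction in words.

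In all, 26 gene lists were fixed before the data were examined, as were the contrasts, the tests and the rule for named genes. They were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, and again with the correlation estimated, and with fry. The lists covered BET and P-TEFb factors, histone genes, MYC and ribosome biogenesis, mesenchymal and EMT genes, epithelial and luminal genes, matrix proteolysis, adhesion and motility, NRF2 targets, ATF4 and the unfolded protein response, heat shock, NF-kB and cytokines, the interferon response, G1/S and replication, G2/M and mitosis, cyclin-dependent kinase inhibitors and p53 targets, apoptosis regulators, homologous recombination, hypoxia and glycolysis, sterol and lipid synthesis, AP-1 and ERK feedback, autophagy and lysosome, Wnt signalling, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear OXPHOS subunits, and markers of leukocytes, endothelium and fibroblasts. Of the 13 mitochondrially encoded mRNAs 0 could be tested, so that list is void and 25 remained. LOX and LOXL2 are among the genes in both the mesenchymal and the matrix proteolysis list.

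Named genes followed a fixed rule. In each contrast between groups they were the 6 largest and 6 smallest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group and replicates that did not overlap, which chance alone gives in 10% of genes for 3 against 3. Symbols of clones and unnamed loci were left out. Per list discussed, up to 4 genes with the smallest adjusted p were named, with up to 2 that moved against the list. MYC, HEXIM1, BRD2, HMOX1, CDKN1A, VIM, CDH1, SNAI2, MMP1, MMP9 and FOSL1 were among the genes named throughout. Some genes that the rule took are not reported here, though they stayed in the tests and counts. For the interaction the rule took the 6 largest and 6 smallest called values with at least 5 CPM in the highest group. Gene positions come from GENCODE v29 on GRCh38, 1-based, matched by symbol: 16233 of 16384 symbols (99.1%) had a position and 16210 (98.9%) a transcript length.

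The pipeline was tested on counts simulated from the means and library sizes of these libraries, with 50 genes changed at each of 4 fold sizes. At folds of 1.25, 1.5, 2 and 4 it recovered 60%, 84%, 94% and 94% in CAR minus DMSO (12597 genes), 54%, 80%, 94% and 98% in JQ1 minus DMSO (12557), 70%, 86%, 86% and 100% in Combination minus DMSO (12553), 72%, 88%, 90% and 96% in Combination minus JQ1 (12562), 64%, 80%, 94% and 98% in Combination minus CAR (12538), and 42%, 74%, 90% and 94% in the interaction (12569). Unchanged genes made up 8.29%, 8.43%, 6.56%, 5.98%, 6.67% and 9.09% of the calls in the same order. In a simulation of CAR minus DMSO with a single list raised 1.3-fold (25 lists, 12580 genes), camera called that list and 1 other.

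The settings varied were RLE, upper-quartile and total count scaling, no expression filter, a strict filter (5 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit to the groups compared alone, glmTreat against a fold of 1.5, leaving out each library in turn, camera with the estimated correlation, fry, and Spearman's in place of Pearson's correlation. Another 3 were added after the data were seen: leaving out both Combination replicate 1 and DMSO replicate 3, offsets corrected for length and GC content, and separate DMSO libraries for CAR and JQ1. All deposited libraries were used.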

Results

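Gene expression was measured by stranded poly(A) RNA sequencing in MDA-MB-231, an established cell line from a triple-negative breast cancer, which lacks the oestrogen and progesterone receptors and HER2 amplification. There were 12 libraries in 4 groups of 3. The vehicle group received DMSO. The CAR group received 10 µmol/L of the agent labelled CAR, which the series title identifies as cardamonin, a chalcone from plants of the ginger family. The JQ1 group received 25 µmol/L of JQ1, which displaces the BET bromodomain proteins from acetylated chromatin, and the Combination group received both. The series title gives the spread of such cells, by invasion and metastasis, as the subject. Total counts per library were 18959419, 17663010 and 19020019 in DMSO, 19754456, 19052492 and 18768318 in CAR, 19010367, 18373704 and 17449715 in JQ1, and 18245928, 18689492 and 18312778 in Combination. The tables listed 16384 genes, and 12645 passed the expression filter. Levels are given as CPM, the count scaled by the total of its library, as mean ± SD with n = 3, and changes as log2 fold change ± SE.

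The drug groups separated far more than the libraries within a group. The first principal component held 84.8% of the variance of log2 CPM and the second 7.87%. Ferritin light chain (FTL), a subunit of the iron store, was the gene that shifted most in its share of the library: 0.309% to 0.373% of the counts in DMSO, 0.608% to 0.64% in CAR, 1.83% to 1.95% in JQ1 and 3.71% to 3.92% in Combination. A pair of libraries stood apart within their groups. DMSO replicate 3 differed from the other DMSO libraries with a dependence on transcript length (Spearman's rho across genes -0.468, against -0.163 to 0.144 in the 9 drug-treated libraries). Each library was set against the mean of the others of its group, so DMSO replicates 1 and 2 (0.396 and 0.406) partly mirror it. Its chi-square per degree of freedom against the other DMSO libraries was 10.6 and 12.6, where the other pairs within groups gave 1.46 to 2.31. Combination replicate 1 carried transcripts typical of liver, with 1429 counts of albumin (ALB) against 4 to 10 in the other 11 libraries.

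**Figure D1:**
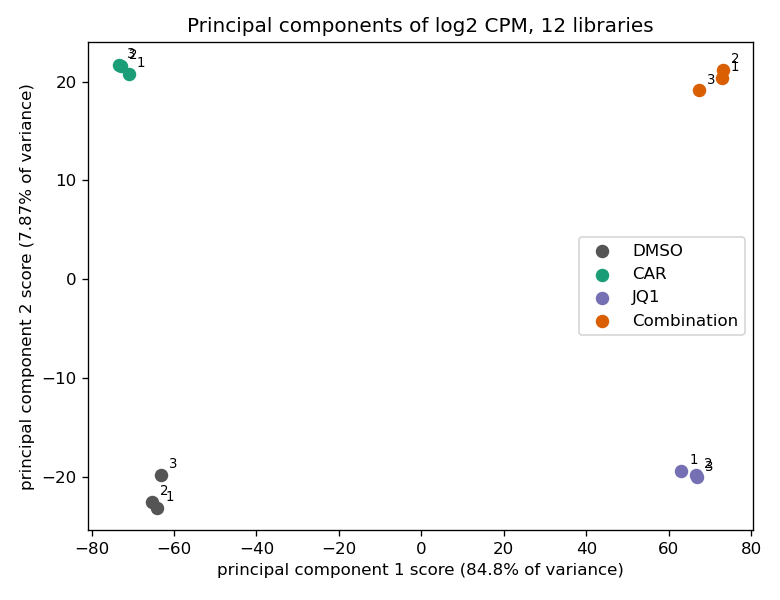
Principal components of the log2 CPM of all tested genes, with component 1 (84.8% of the variance) on the x axis and component 2 (7.87%) on the y axis, and each point 1 of the 12 libraries coloured by group. The 3 libraries of each group lie together.

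The comparison of CAR with DMSO asks what the plant compound does alone. CAR raised the genes of the NRF2 antioxidant programme. Haem oxygenase 1 (HMOX1), which degrades haem, went from 17.8 ± 0.439 to 131 ± 3.68 CPM, a 7.33-fold rise (log2 2.87 ± 0.05). The aldo-keto reductase AKR1B10 rose 26.7-fold from 0.42 ± 0.174 to 11.4 ± 0.921 CPM, and the cystine importer SLC7A11 rose 6.2-fold from 94.1 ± 14.3 to 582 ± 10.5 CPM. The glutathione synthesis subunit GCLM rose 4.31-fold, TRIM16L 3.56-fold and sulfiredoxin (SRXN1) 3.48-fold. Among the other genes that rose most were the thrombin receptor family member F2RL2 (16.6-fold, to 20.8 ± 0.485 CPM), the hexokinase domain gene HKDC1 (5.73-fold) and the lipoprotein lipase inhibitor ANGPTL4 (4.93-fold). The genes that fell most were the synaptotagmin SYT2 (10-fold, 11.3 ± 0.983 to 1.12 ± 0.321 CPM), CEMIP, which takes part in hyaluronan breakdown (7.03-fold, 31.2 ± 4.89 to 4.44 ± 0.711 CPM), the collagen-binding integrin subunit ITGA10 (6.97-fold), the transcription factor SOX4 (5.35-fold), the VIP receptor VIPR1 (5.25-fold, 58.5 ± 0.607 to 11.1 ± 0.757 CPM) and the small GTPase RHOJ (4.86-fold).

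Of 28 NRF2 targets tested, 27 rose and 0 fell, with the same counts when adjusted over the list alone, and the median log2 change was 0.93 (camera with Benjamini-Hochberg adjustment, adjusted p = 3.51e-83). Genes of the MYC and ribosome biogenesis list rose in 32 of 33 cases, with 0 lower (32 and 0 adjusted over the list alone, median 0.61, adjusted p = 1.18e-30). Examples were the ribosome assembly factors RRP12 (2.02-fold, 46.2 ± 1.17 to 93 ± 4.81 CPM) and WDR43 (1.82-fold), the polyamine enzyme ODC1 (1.9-fold) and TCOF1 (1.6-fold), which serves transcription of ribosomal RNA genes. MYC itself rose from 122 ± 0.227 to 166 ± 2.06 CPM (log2 0.45). Both of these calls held with an estimated correlation between the genes of a list (adjusted p = 6.34e-05 and 0.00256). For the other 5 lists called in this comparison the call was lost under that estimate.

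The ATF4 and unfolded protein response list had 15 higher and 3 lower of 24 (18 and 3 adjusted over the list alone, median 0.31, adjusted p = 5.59e-06; adjusted p = 0.131 with an estimated correlation). The stress transcription factors DDIT3 (2.2-fold) and CEBPB (2.09-fold), the amino acid transporter subunit SLC3A2 (1.93-fold) and the phosphatase regulator PPP1R15A (1.76-fold) rose, while VLDLR (log2 -0.38) and the chaperone DNAJB9 (-0.36) fell. Heat shock genes were higher in 14 and lower in 1 of 19 (14 and 1 adjusted over the list alone, median 0.38, adjusted p = 3.48e-08; adjusted p = 0.131 with an estimated correlation). FKBP4 rose 1.69-fold, HSPD1 1.62-fold, STIP1 1.47-fold and the constitutive chaperone HSPA8 1.43-fold (2520 ± 31.7 to 3620 ± 68.7 CPM). HSPA1A was the member that fell (log2 -0.21), a call lost without DMSO replicate 2 or 3 or CAR replicate 1 or 2 (log2 -0.2, -0.18, -0.23 and -0.12) or in a fit to these groups alone (adjusted p = 0.0577). Cyclin-dependent kinase inhibitors and p53 targets were lower in 13 and higher in 2 of 21, also when adjusted over the list alone (median -0.35, adjusted p = 0.0154; adjusted p = 0.131 with an estimated correlation). TP53INP1 fell 1.76-fold, CDKN2C 1.68-fold, the repair factor XPC 1.51-fold and CDKN1B 1.41-fold, against rises of GADD45A (log2 0.30) and FAS (0.38). The FAS call was lost without DMSO replicate 3 (log2 0.32) and with DESeq2 (adjusted p = 0.0841). The hypoxia and glycolysis list had 19 higher and 4 lower of 29, also adjusted over the list alone (median 0.20, adjusted p = 0.00466; adjusted p = 0.365 with an estimated correlation), with GAPDH at 1.36-fold, GPI at 1.35-fold and NDRG1 at 1.29-fold higher, and BNIP3L (log2 -0.46) and P4HA2 (-0.40) lower. Cytosolic ribosomal protein mRNAs were higher in 27 and lower in 0 of 30 (28 and 0 adjusted over the list alone, median 0.27, adjusted p = 2.44e-06; adjusted p = 0.549 with an estimated correlation), with RPLP0 at 1.28-fold, RPL27 at 1.27-fold and RPS18 at 1.26-fold. The length trend of DMSO replicate 3 bears on short transcripts such as these, and the list's median was 0.35 without that library.

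Lists tied to invasion were not called in CAR against DMSO with all libraries. Mesenchymal and EMT genes were 4 higher and 16 lower of 28 (adjusted p = 0.102), adhesion and motility genes 5 and 16 of 30 (adjusted p = 0.132), matrix proteolysis genes 8 and 11 of 24 (adjusted p = 0.373), and epithelial and luminal genes 3 and 5 of 15 (adjusted p = 0.76). Without DMSO replicate 3 the lists called went from 7 to 11. Those gained were the mesenchymal and EMT list (median -0.23 against -0.20, adjusted p = 0.0131), adhesion and motility (-0.10 against -0.12, adjusted p = 0.0131), sterol and lipid synthesis (-0.07 against -0.08, adjusted p = 0.0226) and G2/M (0.13 against 0.14, adjusted p = 0.0478). The sterol list was called as well with total count scaling (adjusted p = 0.0333) and with length and GC correction (0.0399), and histone genes were called without DMSO replicate 2 (median -0.21, adjusted p = 0.048). Vimentin (VIM) was 2110 ± 78.4 in DMSO and 2150 ± 4.36 CPM in CAR (log2 0.03, adjusted p = 0.566 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; the sign flips to -0.04 with total count scaling and -0.01 with upper-quartile scaling). Without DMSO replicate 3 it passed as higher (log2 0.06, adjusted p = 0.0453). The collagenase MMP1 (3.86 and 4.82 CPM) and SNAI2 (33.1 and 34.9 CPM) did not pass the test. MMP1 passed as higher with the replicate number as a block (log2 0.32, adjusted p = 0.0427) and without DMSO replicate 1 (0.46, adjusted p = 0.0328). BRD2 was at 423 ± 4.16 and 423 ± 5.81 CPM (log2 0.00, with the sign flipped to -0.06 under total count scaling). E-cadherin (CDH1, 0.425 ± 0.327 CPM in DMSO) and MMP9 (0.17 CPM) were too low to be tested. Nor were calls made with all libraries for BET and P-TEFb factors (5 higher and 2 lower of 18), histone genes (0 and 3 of 10), NF-kB and cytokines (5 and 9 of 23), the interferon response (5 and 16 of 29), G1/S and replication (10 and 7 of 30), G2/M and mitosis (15 and 4 of 29), apoptosis regulators (6 and 10 of 23), homologous recombination (7 and 3 of 18), sterol and lipid synthesis (3 and 13 of 27), AP-1 and ERK feedback (6 and 6 of 20), autophagy and lysosome (4 and 5 of 22), Wnt signalling (0 and 8 of 15), nuclear OXPHOS subunits (7 and 2 of 25) or markers of leukocytes, endothelium and fibroblasts (1 and 3 of the 6 tested of 20). Adjusted over the list alone the pairs of higher and lower counts differed only for BET and P-TEFb factors (2 and 2), histone genes (0 and 2), G1/S (15 and 7), apoptosis (7 and 10), Wnt (0 and 7) and OXPHOS (6 and 2).

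In all, 3449 genes were higher and 3801 lower in CAR than in DMSO, 57.3% of those tested, of which 117 and 436 changed at least 2-fold. The median absolute log2 change was 0.224. HMOX1 (chromosome 22, 35380361 to 35394214, plus strand) had the smallest adjusted p among the named genes, 3.11e-20 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and AKR1B10 (chromosome 7, 134527592 to 134541408, plus strand) had 6.13e-13. With total count scaling the split moved to 2636 higher and 4738 lower, so the higher share fell from 47.6% to 35.7%.

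The comparison of JQ1 with DMSO asks what BET inhibition does alone. JQ1 lowered the genes of the cell cycle and raised poly(A) transcripts of histone genes. All 29 genes of the G2/M and mitosis list fell, with a median log2 change of -3.62. Cyclin B1 (CCNB1) went from 236 ± 10.2 to 18.6 ± 1.42 CPM, a 12.7-fold fall, and thymidylate synthase (TYMS) from 330 ± 8.77 to 40.6 ± 1.6 CPM, an 8.1-fold fall. HEXIM1, the inhibitor of the elongation factor P-TEFb, rose 4.2-fold from 143 ± 8.73 to 601 ± 2.05 CPM (log2 2.07 ± 0.04), and MYC was 122 ± 0.227 and 126 ± 2.3 CPM. MYC did not pass the test (log2 0.05 ± 0.04, adjusted p = 0.198 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and its sign flips to -0.07 with total count scaling and -0.01 with upper-quartile scaling. With length and GC correction it passed as higher (log2 0.08, adjusted p = 0.029).

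The genes that rose most included ID3, a dominant-negative helix-loop-helix factor (36.1-fold, 5.27 ± 1.15 to 191 ± 4.43 CPM), the presynaptic scaffold BSN (36.1-fold), VWA5B2 (31-fold), EFR3B, a plasma membrane adaptor (28.7-fold, 3.26 ± 0.723 to 93.8 ± 2.51 CPM), and the histone gene H4C8 (25.5-fold). The phosphatase DUSP9 had 3 counts over the DMSO libraries and 271 over the JQ1 libraries, a ratio of 88.1 with a 95% counting interval of 33.7 to 486. The genes that fell most were the organic anion transporter SLCO4A1 (70.3-fold, 68.2 ± 1.36 to 0.956 ± 0.281 CPM), SYT2 (58.8-fold), the endothelial guidance receptor ROBO4 (52.8-fold, 29.7 ± 0.476 to 0.553 ± 0.0871 CPM), DMBT1 (50.6-fold), TMEM71 (43.6-fold) and the inflammasome sensor NLRP3 (41.6-fold, 9.51 ± 0.549 to 0.221 ± 0.105 CPM). The fall of SYT2 was log2 -5.88, and -7.47 without JQ1 replicate 1. The rise of DUSP9 was log2 6.46, and 7.28 without DMSO replicate 3.

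The counts adjusted over the list alone equalled those over all genes for every list named in this comparison. All 10 histone genes tested of 16 listed rose (median 3.33, camera adjusted p = 3.93e-12). H2BC21 rose 15.1-fold, H2BC5 14.2-fold (19.1 ± 1.65 to 271 ± 3.26 CPM), H2BC4 11.1-fold and H2AC6 9.16-fold. Histone genes are near-identical copies, and reads may be split between them. The libraries hold poly(A) RNA, so histone transcripts without a poly(A) tail were not measured, and total histone mRNA is not known. G2/M genes fell in 29 of 29 (adjusted p = 6.16e-53), including the spindle checkpoint kinase BUB1 (6.73-fold), the kinesin KIF11 (5.51-fold) and DLGAP5 (11.7-fold). G1/S and replication genes fell in 30 of 30 (median -2.13, adjusted p = 3.19e-32), including the ribonucleotide reductase subunit RRM1 (5-fold), the helicase subunit MCM3 (4.44-fold) and UHRF1 (13.8-fold). Homologous recombination genes were lower in 16 and higher in 2 of 18 (median -2.68, adjusted p = 5.14e-14): FANCD2 fell 19.7-fold, RAD51AP1 14.5-fold, FANCI 6.76-fold and the checkpoint kinase CHEK1 6.51-fold, while ATR (log2 0.25) and ATM (0.35) rose. The ATM call was lost without JQ1 replicate 2 (log2 0.32) and with length and GC correction (adjusted p = 0.0506), and both calls were lost with total count scaling (adjusted p = 0.0643 for ATR and 0.0969 for ATM). Autophagy and lysosome genes were higher in 20 and lower in 2 of 22 (median 0.83, adjusted p = 2.58e-06). The sialidase NEU1 rose 4.21-fold (86.8 ± 6.85 to 365 ± 12.2 CPM), MAP1LC3B 2.96-fold, CTSA 2.35-fold and LAMP1 1.89-fold, against falls of TFEB (log2 -0.68) and ATG5 (-0.30). These 5 calls held with an estimated correlation (adjusted p = 0.0129 for 4 of them and 0.0153 for homologous recombination), and the 8 calls that follow were lost.

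Mesenchymal and EMT genes were lower in 23 and higher in 2 of 28 (median -0.87, adjusted p = 2.31e-05; adjusted p = 0.0511 with an estimated correlation). COL4A2 fell 4.03-fold, the collagen crosslinker LOX 3.91-fold and COL5A1 3.32-fold, VIM went from 2110 ± 78.4 to 886 ± 13.9 CPM (log2 -1.25), and COL6A1 (log2 0.90) and FSTL1 (0.56) rose. Adhesion and motility genes were lower in 17 and higher in 6 of 30 (median -0.23, adjusted p = 0.0191; adjusted p = 0.177 with an estimated correlation). LAMB3 fell 4.52-fold, caveolin 1 (CAV1) 3.31-fold, ITGB5 2.98-fold and the focal adhesion protein ZYX 2.96-fold, and ITGB3 rose 3.25-fold and ITGA1 2.37-fold. NF-kB and cytokine genes were lower in 20 and higher in 2 of 23 (median -1.55, adjusted p = 0.000175; adjusted p = 0.0511 with an estimated correlation): LIF fell 21.6-fold (39.4 ± 3.05 to 1.81 ± 0.336 CPM), ICAM1 8.69-fold, TNFAIP2 8.21-fold and IER3 3.3-fold, and NFKBIA (log2 0.57) and SOD2 (0.65) rose. AP-1 and ERK feedback genes were lower in 13 and higher in 4 of 20 (median -0.51, adjusted p = 0.0057; adjusted p = 0.0511 with an estimated correlation), among them ETV4 (17.1-fold), FOSL1 (10.5-fold, 323 ± 15 to 30.9 ± 2.01 CPM), SPRY4 (3.4-fold) and DUSP5 (2.72-fold) lower, and JUND (5.12-fold) and JUNB (log2 0.72) higher. Interferon response genes were lower in 21 and higher in 5 of 29 (median -1.68, adjusted p = 0.0283; adjusted p = 0.0645 with an estimated correlation, 0.0774 without DMSO replicate 3, where the median was -1.66, and 0.0542 with length and GC correction). IFI44 fell 9.84-fold, IFIT3 5.56-fold and IFIT2 3.2-fold, and IFI6 rose 4.15-fold and STAT2 2.23-fold.

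NRF2 targets were higher in 18 and lower in 7 of 28 (median 0.56, adjusted p = 1.88e-05; adjusted p = 0.0645 with an estimated correlation). FTL rose 6.16-fold (3100 ± 319 to 19100 ± 687 CPM), SRXN1 5.44-fold, thioredoxin reductase (TXNRD1) 3.4-fold and glutathione reductase (GSR) 3.13-fold, whereas the carbonyl reductase CBR3 fell 7.61-fold and HMOX1 2.16-fold. MYC and ribosome biogenesis genes were lower in 25 and higher in 4 of 33 (median -0.56, adjusted p = 0.0084; adjusted p = 0.266 with an estimated correlation). TCOF1 fell 4-fold, DCTPP1 3.79-fold, DKC1 2.09-fold and PA2G4 1.99-fold, and ODC1 (log2 0.83) and IMPDH2 (0.68) rose. BET and P-TEFb factors were higher in 10 and lower in 4 of 18 (median 0.27, adjusted p = 0.027; adjusted p = 0.156 with an estimated correlation): besides HEXIM1, BRD2 rose 2.16-fold (423 ± 4.16 to 914 ± 17.6 CPM), SUPT5H 2-fold and ELL2 1.5-fold, and LARP7 (log2 -0.31) and CDK9 (-0.18) fell. The cell cycle inhibitor CDKN1A rose (55.9 ± 1.47 to 167 ± 1.44 CPM, log2 1.58) in a list of p53 targets and kinase inhibitors that was not called (13 higher and 7 lower of 21, adjusted p = 0.063). Epithelial and luminal genes (3 and 10 of 15, adjusted p = 0.0501) and matrix proteolysis genes (7 and 13 of 24, adjusted p = 0.063) were not called either. The epithelial list was called with the replicate number as a block (adjusted p = 0.0468), RLE scaling (0.0495), total count scaling (0.0474) and length and GC correction (0.0378). The matrix list was called with total count scaling (0.0474), without DMSO replicate 3 (0.0495, median -0.18 either way) and with length and GC correction (0.0488), as was the list of p53 targets with that correction (0.0488).

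JQ1 against DMSO gave 5247 genes higher and 5333 lower, 83.7% of those tested, with 1485 and 2303 of them changed at least 2-fold and a median absolute log2 change of 0.604. SLCO4A1 (chromosome 20, 62642445 to 62685785, plus strand) had an adjusted p = 8.94e-22, ID3 (chromosome 1, 23557918 to 23559794, minus strand) 2.77e-22 and HEXIM1 (chromosome 17, 45148502 to 45152101, plus strand) 4.52e-21, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With so many genes changed, the zero of the scale is set by the normalization, and total count scaling moved the median of all genes by -0.119.

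**Figure D2:**
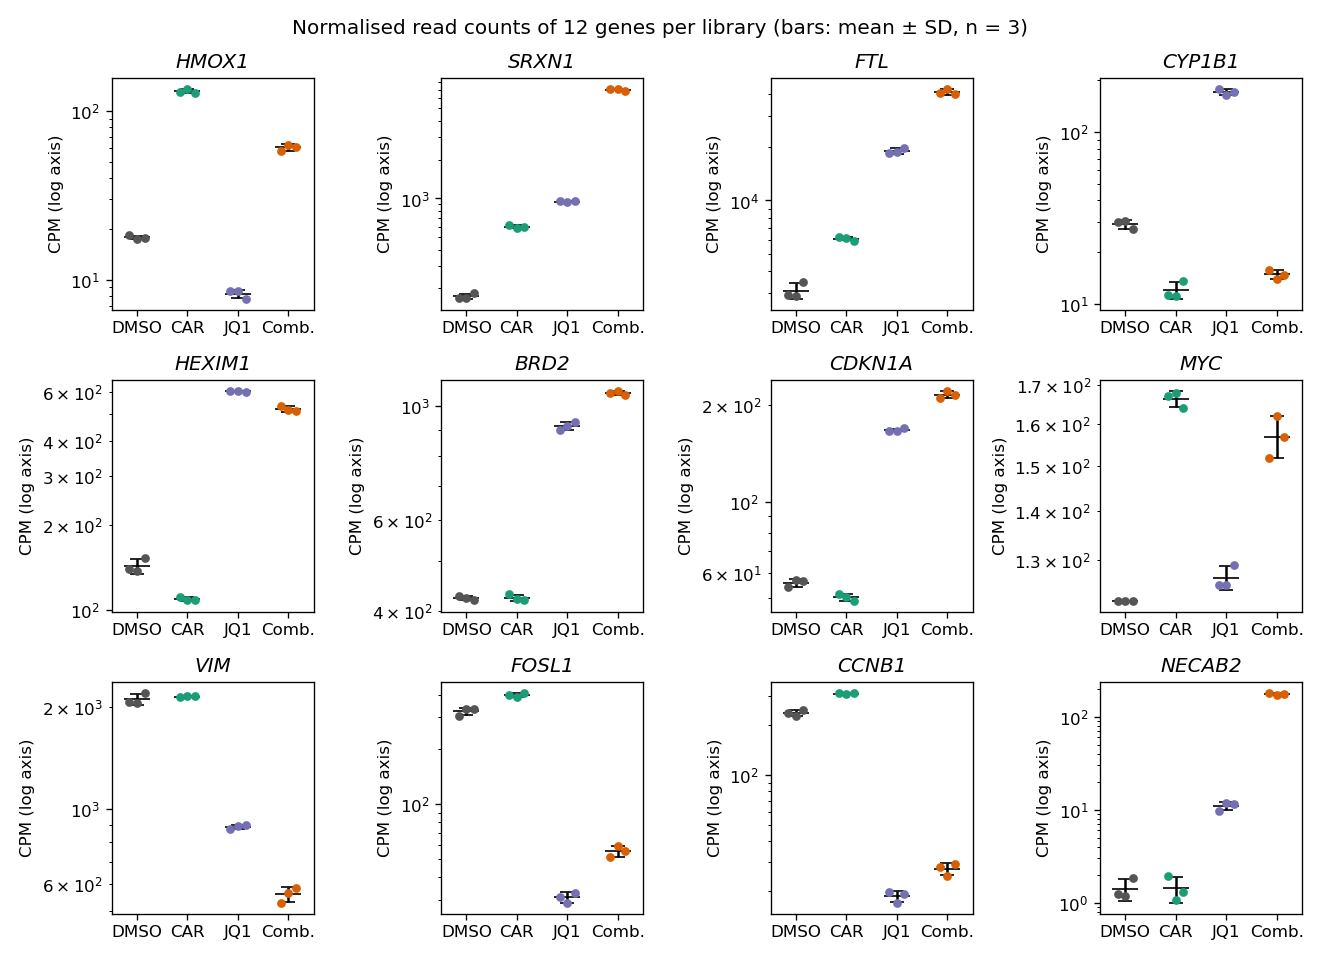
CPM of 12 named genes (log scale on the y axis) in the 4 groups on the x axis, with each point 1 library and the bar and whiskers the mean ± SD of 3 libraries. HMOX1 is highest in CAR (131 CPM), SRXN1, FTL and NECAB2 are highest in Combination (6990, 40900 and 175 CPM), and CCNB1 and FOSL1 are low in both groups that received JQ1.

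The comparison of Combination with DMSO asks what both agents do together. Most NRF2 targets were higher than in DMSO, and the genes of the cell cycle were lower. SRXN1 rose 40.3-fold from 173 ± 8.07 to 6990 ± 99.2 CPM (log2 5.33 ± 0.04), OSGIN1 22.5-fold from 25.2 ± 1.9 to 569 ± 18.3 CPM, GCLM 12.2-fold from 91.3 ± 2.15 to 1120 ± 32.2 CPM and GSR 9.43-fold. The largest rise was that of NECAB2, a neuronal calcium-binding protein, from 1.42 ± 0.38 to 175 ± 4.47 CPM (122-fold, log2 6.93 ± 0.10). VIM fell from 2110 ± 78.4 to 560 ± 28.7 CPM (3.77-fold). Other genes with the largest rises were H4C8 (33.2-fold), VWA5B2 (30.7-fold), EFR3B (29-fold) and ID3 (26.1-fold). The largest falls were those of SLCO4A1 (93.5-fold, 68.2 ± 1.36 to 0.723 ± 0.0909 CPM), RHOJ (76.2-fold), the claudin CLDN2 (70.5-fold), SIGIRR, a negative regulator of interleukin 1 signalling (62.6-fold), SYT2 (61.8-fold) and PIK3CG (43.1-fold). CLDN2, SYT2 and PIK3CG had only 4, 9 and 8 counts over the Combination libraries, so these folds are imprecise. RHOJ had log2 -6.25, and -8.01 without Combination replicate 3, and CLDN2 -6.14, and -7.38 without Combination replicate 1.

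Counts adjusted over the list alone equalled those over all genes for the lists called in this comparison. The 9 calls that held with an estimated correlation were as follows. NRF2 targets were higher in 25 and lower in 2 of 28 (median 1.54, camera adjusted p = 6.61e-28, and 0.00293 with the estimate), the lower ones being UGDH (log2 -0.48) and CBR3 (-2.46). G2/M genes fell in 29 of 29 (median -3.68, adjusted p = 7.92e-48, and 0.00926). CCNB1 fell 8.65-fold, DLGAP5 13.9-fold and BUB1 6.75-fold. G1/S genes fell in 30 of 30 (median -2.17, adjusted p = 1.54e-30, and 0.00899). RRM2 fell 18-fold (176 ± 2.41 to 9.76 ± 1.84 CPM), TYMS 12-fold and MCM6 6.06-fold. Homologous recombination genes were lower in 16 and higher in 1 of 18 (median -2.96, adjusted p = 2.42e-13, and 0.016). RAD51AP1 fell 29.4-fold. Histone genes were higher in 9 and lower in 1 of 10 (median 3.28, adjusted p = 3.23e-10, and 0.016): H2BC21 rose 20.9-fold and H2BC5 13.9-fold. Autophagy and lysosome genes were higher in 19 and lower in 2 of 22 (median 0.87, adjusted p = 2.86e-08, and 0.00926). The lysosomal channel MCOLN1 rose 6.78-fold, NEU1 6.69-fold and MAP1LC3B 3.5-fold. Hypoxia and glycolysis genes were higher in 26 and lower in 3 of 29 (median 0.63, adjusted p = 4.95e-08, and 0.0486): the vasodilator peptide ADM rose 9.49-fold (40.4 ± 3.52 to 384 ± 12.9 CPM), P4HA1 4.68-fold, NDRG1 3.52-fold and BNIP3 3.14-fold, and the hypoxia markers VEGFA (3.39-fold) and CA9 (5.46-fold) fell. Mesenchymal and EMT genes were lower in 23 and higher in 2 of 28 (median -1.20, adjusted p = 1.51e-06, and 0.0282). COL5A1 fell 4.85-fold, COL4A2 4.79-fold and S100A4 3.89-fold, and the EMT transcription factor SNAI1 rose 2.88-fold (0.954 ± 0.19 to 2.77 ± 0.258 CPM). COL6A1 had log2 0.15, which turned to -0.05 with total count scaling and lost its call without DMSO replicate 1 or 3 or Combination replicate 2 or 3 (0.14, 0.15, 0.13 and 0.13). That call was also lost with RLE and upper-quartile scaling, the strict filter, the replicate number as a block, DESeq2 and a fit to these groups alone (adjusted p = 0.0588, 0.282, 0.0802, 0.0556, 0.108 and 0.0796). AP-1 and ERK feedback genes were lower in 13 and higher in 6 of 20 (median -0.49, adjusted p = 0.00742, and 0.0486). ETV4 fell 15.5-fold, FOSL1 5.83-fold and DUSP6 2.95-fold, and JUND rose 4.86-fold.

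A further 5 calls were lost with the estimate. Epithelial and luminal genes were lower in 10 and higher in 3 of 15 (median -0.98, adjusted p = 0.0153; adjusted p = 0.05003 with an estimated correlation). CLDN7 fell 11.7-fold, KRT7 6.74-fold (144 ± 3.29 to 21.4 ± 0.967 CPM), the desmosome protein DSP 3.47-fold and KRT18 1.97-fold, and CLDN4 (log2 0.45) and TJP1 (0.55) rose. Adhesion and motility genes were lower in 22 and higher in 6 of 30 (median -0.33, adjusted p = 0.00591; adjusted p = 0.12 with an estimated correlation). ITGB5 fell 5.17-fold, CAV1 5.03-fold and ZYX 3-fold, and ITGB3 rose 4.61-fold and CCN2 1.75-fold. BET and P-TEFb factors were higher in 14 and lower in 4 of 18 (median 0.52, adjusted p = 0.00992; adjusted p = 0.11 with an estimated correlation). HEXIM1 rose 3.63-fold, BRD2 2.51-fold and SUPT5H 2.32-fold, and LARP7 (log2 -0.55) and CCNT2 (-0.37) fell. NF-kB and cytokine genes were lower in 19 and higher in 2 of 23 (median -1.62, adjusted p = 0.00054; adjusted p = 0.05003 with an estimated correlation). LIF fell 14.5-fold and ICAM1 6.08-fold. Interferon response genes were lower in 20 and higher in 5 of 29 (median -1.77, adjusted p = 0.0457; adjusted p = 0.074 with an estimated correlation). IFI44 fell 10.9-fold and IFI6 rose 5.9-fold. That call was also lost without DMSO replicate 2 (0.0525), DMSO replicate 3 (0.139) or Combination replicate 2 (0.0526), with medians of -1.53, -1.74 and -1.76. It was lost with total count scaling (0.0989) and with length and GC correction (0.117) as well. MYC and ribosome biogenesis genes (11 higher and 18 lower of 33, 11 and 19 adjusted over the list alone, adjusted p = 0.364) and matrix proteolysis genes (8 and 13 of 24, adjusted p = 0.186) were not called, and MYC rose from 122 ± 0.227 to 157 ± 5.01 CPM (log2 0.37).

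In Combination against DMSO 5386 genes were higher and 5415 lower, 85.4% of those tested, with 1586 and 2573 changed at least 2-fold. SRXN1 (chromosome 20, 646615 to 653370, minus strand) had an adjusted p = 2.59e-27 and NECAB2 (chromosome 16, 83968632 to 84002776, plus strand) 5.23e-23 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. NECAB2 starts 2300 bp after the end of OSGIN1 (chromosome 16, 83948282 to 83966332) on the same strand. With total count scaling the split was 4216 higher and 6501 lower (39.3% higher, against 49.9%), and the median of all genes moved by -0.207.

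**Figure D3:**
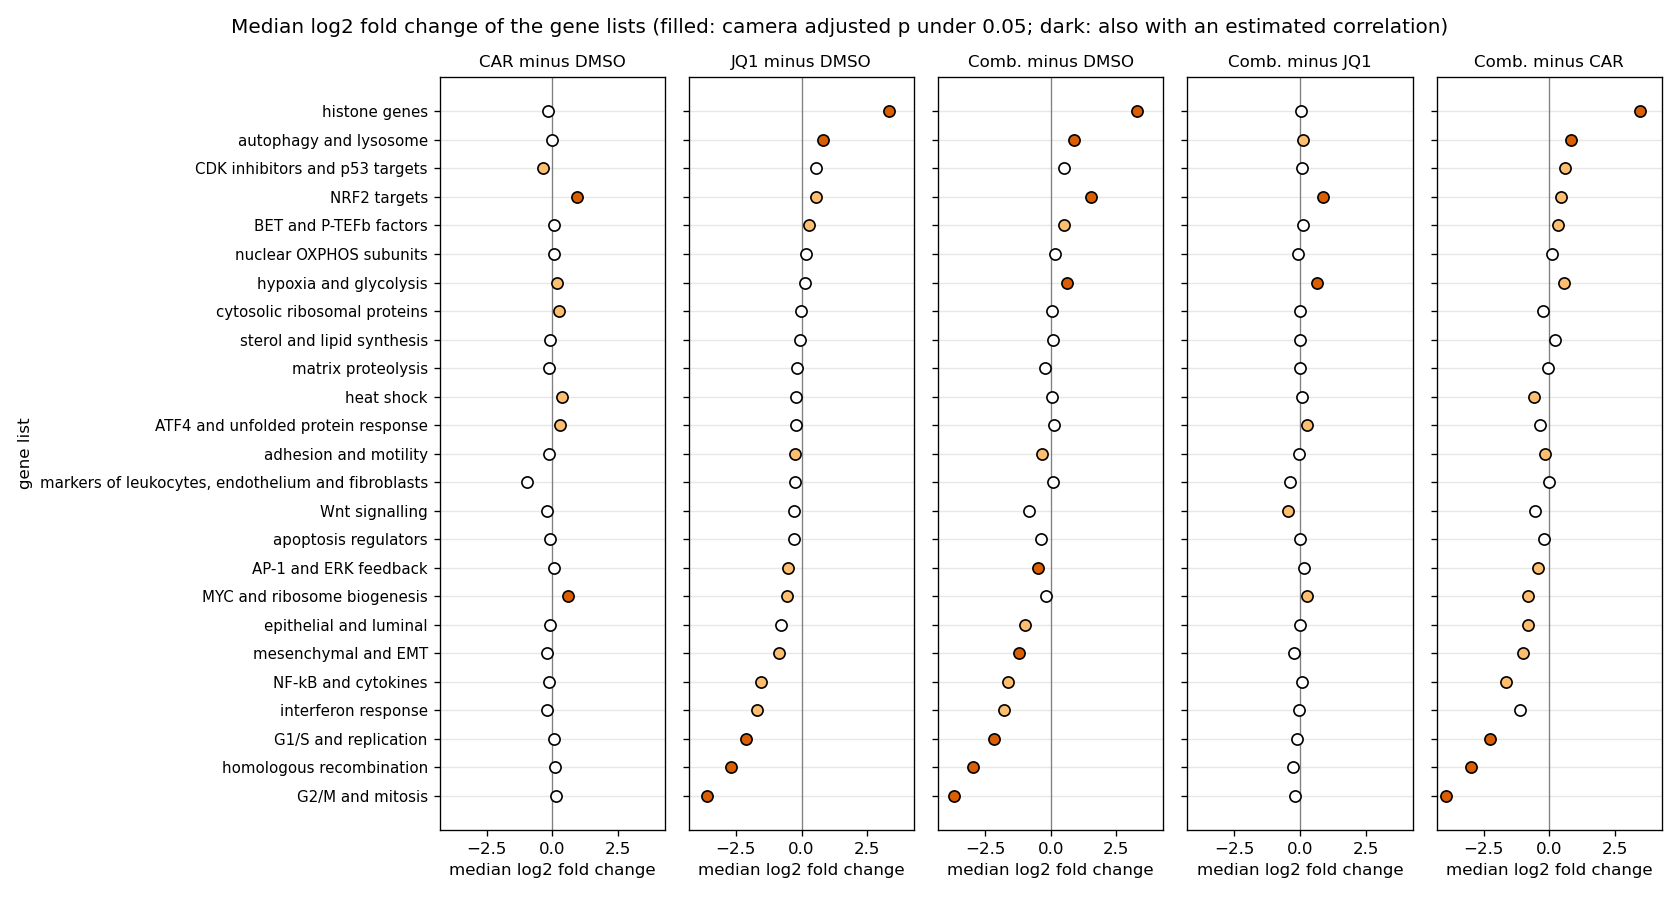
Median log2 fold change (x axis) of the genes of each tested list (y axis) in the 5 comparisons between groups, one panel each. Open points mark lists with a camera adjusted p of at least 0.05, light points lists called with the preset correlation alone, and dark points lists called also with an estimated correlation; the G2/M list lies at -3.62 in JQ1 minus DMSO and the NRF2 list at 0.93 in CAR minus DMSO.

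The comparison of Combination with JQ1 asks what CAR adds to the BET inhibitor. Again the NRF2 targets rose, and with them the genes of hypoxia and glycolysis. NECAB2 rose 15.9-fold from 11 ± 1.12 to 175 ± 4.47 CPM, OSGIN1 11.5-fold from 49.4 ± 1.87 to 569 ± 18.3 CPM, GCLM 9.41-fold and SRXN1 7.4-fold from 944 ± 9.75 to 6990 ± 99.2 CPM. The cytochrome P450 gene CYP1B1, a target of the aryl hydrocarbon receptor, fell 11.6-fold from 172 ± 6.26 to 14.8 ± 0.932 CPM (log2 -3.53 ± 0.06), and its relative CYP1A1 fell 5.47-fold from 22 ± 1.51 to 4.02 ± 0.166 CPM. JAKMIP3 (9.44-fold) and F2RL2 (7.72-fold) were among the largest rises, and NAALAD2 (7.09-fold), the actin-crosslinking substrate of protein kinase C MARCKS (5.08-fold, 38.9 ± 1.91 to 7.66 ± 0.705 CPM), DUSP9 (4.34-fold) and THSD1 (4.1-fold) among the largest falls.

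NRF2 targets were higher in 24 and lower in 1 of 28 (25 and 1 adjusted over the list alone, median 0.87, camera adjusted p = 2.74e-97, and 5.63e-05 with an estimated correlation). The autophagy receptor SQSTM1 rose 4.38-fold (746 ± 16.8 to 3270 ± 73.6 CPM) and AKR1C3 fell (log2 -0.36). Hypoxia and glycolysis genes were higher in 27 and lower in 0 of 29, also adjusted over the list alone (median 0.66, adjusted p = 1.12e-29, and 0.00346 with an estimated correlation): BNIP3 rose 2.41-fold, P4HA1 2.12-fold, LDHA 1.9-fold (2190 ± 8.56 to 4150 ± 74.2 CPM) and GAPDH 1.86-fold. The other 4 calls were lost with the estimate. MYC and ribosome biogenesis genes were higher in 28 and lower in 0 of 33, also adjusted over the list alone (median 0.28, adjusted p = 1.36e-05; adjusted p = 0.175 with an estimated correlation), with RRP12 at log2 0.64, GNL3 at 0.57, PES1 at 0.56 and NOP56 at 0.41. ATF4 and unfolded protein response genes were higher in 13 and lower in 3 of 24, also adjusted over the list alone (median 0.28, adjusted p = 0.00175; adjusted p = 0.276 with an estimated correlation). Asparagine synthetase (ASNS) rose 2.95-fold, SLC3A2 1.89-fold and PPP1R15A 1.81-fold, and SLC7A5 (1.98-fold, 1690 ± 17.1 to 854 ± 34.2 CPM) and DNAJB9 (1.4-fold) fell. Autophagy and lysosome genes were higher in 11 and lower in 2 of 22 (11 and 3 adjusted over the list alone, median 0.10, adjusted p = 0.00456; adjusted p = 0.151 with an estimated correlation), led by MCOLN1 (2.31-fold) and NEU1 (1.59-fold), with ATG16L1 lower (log2 -0.18). Wnt signalling genes were lower in 9 and higher in 0 of 15, also adjusted over the list alone (median -0.45, adjusted p = 0.00315; adjusted p = 0.0573 with an estimated correlation). DKK1 fell 1.89-fold, TCF7L2 1.56-fold, FZD7 1.52-fold and FZD2 1.37-fold.

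Mesenchymal and EMT genes were 6 higher and 14 lower of 28 and the list was not called (adjusted p = 0.0805; 0.0129 without both libraries that stood apart and 0.00993 with length and GC correction), though VIM fell from 886 ± 13.9 to 560 ± 28.7 CPM (log2 -0.66) and SNAI2 rose from 19 to 28.7 CPM (log2 0.59). G1/S (4 higher and 11 lower of 30, adjusted p = 0.267), G2/M (5 and 7 of 29, adjusted p = 0.576) and histone genes (4 and 3 of 10, adjusted p = 0.691) were not called either. In all, 3292 genes were higher and 3275 lower in Combination than in JQ1, 51.9% of those tested, with 163 and 308 changed at least 2-fold. CYP1B1 (chromosome 2, 38066973 to 38109902, minus strand) had an adjusted p = 1.28e-20 and GCLM (chromosome 1, 93885205 to 93909456, minus strand) 1.16e-23 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With total count scaling the split was 2229 higher and 4554 lower (32.9% higher, against 50.1%).

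The comparison of Combination with CAR asks what the BET inhibitor adds to CAR. Cell cycle genes fell and poly(A) transcripts of histone genes rose, as in JQ1 against DMSO. NECAB2 rose 121-fold from 1.44 ± 0.441 to 175 ± 4.47 CPM. VWA5B2 had 3 counts over the CAR libraries and 301 over the Combination libraries, a ratio of 102 with a 95% counting interval of 39.1 to 563. EFR3B rose 45.1-fold (2.09 ± 0.151 to 94.5 ± 0.495 CPM), BSN 39.3-fold and the tubulin polymerization factor TPPP 37.5-fold. TESMIN fell 74.5-fold, the hyaluronan synthase HAS2 62.4-fold (10.2 ± 0.681 to 0.156 ± 0.089 CPM), SLCO4A1 46.2-fold, FAT3 45-fold, TMEM71 44-fold and RIMS2 43.2-fold. TESMIN, HAS2 and FAT3 had 4, 8 and 6 counts over the Combination libraries and BSN 9 over the CAR libraries, under 3 per library on average or at it, so these folds are imprecise. VWA5B2 had log2 6.67, and 7.52 without CAR replicate 2.

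Among the lists, G2/M genes fell in 29 of 29 (median -3.94, camera adjusted p = 1.64e-47, and 0.0164 with an estimated correlation). KIF23 fell 18.1-fold and CCNB1 11.3-fold. G1/S genes fell in 30 of 30 (median -2.25, adjusted p = 1.86e-29, and 0.0164). RRM2 fell 19.4-fold. Homologous recombination genes were lower in 16 and higher in 1 of 18 (median -3.00, adjusted p = 6.99e-14, and 0.027). CHEK1 fell 8.55-fold. Histone genes rose in 10 of 10 (median 3.48, adjusted p = 2.55e-11, and 0.0413). H2BC21 rose 31.1-fold. Autophagy and lysosome genes were higher in 19 and lower in 2 of 22 (median 0.82, adjusted p = 1.2e-07, and 0.0164). CTSA rose 3.29-fold. The counts adjusted over the list alone were the same for these 5 lists, and these calls held with the estimate. Of the 11 calls that were lost with it, MYC and ribosome biogenesis genes were lower in 29 and higher in 1 of 33 (median -0.82, adjusted p = 2.39e-06; adjusted p = 0.0828 with an estimated correlation). TCOF1 fell 5.63-fold, WDR43 2.74-fold and PA2G4 2.4-fold. IMPDH2 was the higher member (log2 0.14, and -0.01 with total count scaling). Mesenchymal and EMT genes were lower in 21 and higher in 4 of 28 (median -1.01, adjusted p = 8.51e-05; adjusted p = 0.0756 with an estimated correlation). VIM fell 3.84-fold. Heat shock genes were lower in 13 and higher in 5 of 19 (median -0.57, adjusted p = 0.0148; adjusted p = 0.368 with an estimated correlation). The collagen chaperone SERPINH1 fell 5.26-fold, HSPH1 2.82-fold and HSPA8 2.59-fold, and the stress-inducible HSPA1B rose 2.38-fold. HSPA1A and HSPA1B are near-identical, and their split is uncertain.

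NRF2 targets were higher in 17 and lower in 7 of 28 (18 and 7 adjusted over the list alone, median 0.43, adjusted p = 1.11e-05; adjusted p = 0.0828 with an estimated correlation). SRXN1 rose 11.6-fold and TXNRD1 3.21-fold, and AKR1B10 fell 40.7-fold and HMOX1 2.15-fold. AKR1B10 had log2 -5.35, and -6.53 without Combination replicate 3. Hypoxia and glycolysis genes were higher in 21 and lower in 5 of 29 (median 0.57, adjusted p = 3.73e-05; adjusted p = 0.0928 with an estimated correlation). ADM rose 8.62-fold and the histone demethylase KDM3A 3.05-fold, and CA9 fell 20.8-fold. Cyclin-dependent kinase inhibitors and p53 targets were higher in 15 and lower in 5 of 21 (median 0.59, adjusted p = 0.0279; adjusted p = 0.0928 with an estimated correlation, and 0.0511 with a median of 0.55 without both libraries that stood apart). TP53INP1 rose 4.99-fold, CDKN1A 4.26-fold and TP53I3 4.24-fold, and FAS fell 7.59-fold and DDB2 4.97-fold. NF-kB and cytokine genes were lower in 19 and higher in 3 of 23 (median -1.65, or -1.47 with the genes near a count of 0 held at their bound, adjusted p = 0.00333; adjusted p = 0.0928 with an estimated correlation). IL11 fell 23.4-fold and LIF 19.6-fold. AP-1 and ERK feedback genes were lower in 14 and higher in 5 of 20 (6 higher adjusted over the list alone, median -0.42, adjusted p = 0.0256; adjusted p = 0.0828 with an estimated correlation). ETV4 fell 16-fold and JUND rose 8.48-fold. Adhesion and motility genes were lower in 18 and higher in 7 of 30 (median -0.17, adjusted p = 0.0356; adjusted p = 0.235 with an estimated correlation). The kinase SRC fell 7.5-fold. BET and P-TEFb factors were higher in 11 and lower in 4 of 18 (median 0.33, adjusted p = 0.0263; adjusted p = 0.158 with an estimated correlation). Epithelial and luminal genes were lower in 9 and higher in 3 of 15 (median -0.80, adjusted p = 0.0263; adjusted p = 0.0828 with an estimated correlation). The splicing regulator ESRP2 fell 10.7-fold and ERBB3 rose 1.78-fold. The call of this list was lost without Combination replicate 3 (adjusted p = 0.0541, median -0.20). Apart from NRF2 targets and AP-1, the counts adjusted over the list alone were the same for all 11. Cytosolic ribosomal protein mRNAs were 2 higher and 23 lower of 30 and not called (adjusted p = 0.165; 0.0289 without both libraries that stood apart).

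Combination against CAR gave 5361 genes higher and 5439 lower, 85.4% of those tested, with 1970 and 2518 changed at least 2-fold and a median absolute log2 change of 0.701. MYC was 166 ± 2.06 in CAR and 157 ± 5.01 CPM in Combination, at the edge of the threshold (log2 -0.08, adjusted p = 0.0495 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the call was lost without any of the 3 CAR libraries (log2 -0.08, -0.07 and -0.09) or without Combination replicate 1 or 3 (-0.06 and -0.08). It was lost as well with no filter, the replicate number as a block and DESeq2 (adjusted p = 0.0707, 0.0614 and 0.0566).

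The interaction asks whether the change from DMSO to Combination differed from the sum of the changes under each agent on the log2 scale. Hypoxia and glycolysis genes lay above that sum, and ribosome biogenesis genes, chaperones and ribosomal protein mRNAs lay below it. The calls of the last 3 of these lists were lost with an estimated correlation (adjusted p = 0.0765, 0.15 and 0.519). BNIP3, a mitophagy receptor, was 179 ± 8.17 CPM in DMSO, 213 ± 4.29 in CAR, 233 ± 3.15 in JQ1 and 562 ± 16.1 in Combination (interaction log2 1.02 ± 0.05), and LDHA was 1880 ± 43.6, 2120 ± 31.6, 2190 ± 8.56 and 4150 ± 74.2 CPM (0.75 ± 0.05). HMOX1 lay on the sum, at 0.00 (adjusted p = 0.987 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the sign flipped to -0.12 with length and GC correction), and VIM below it, at -0.69. The largest value was that of NECAB2 (3.98 ± 0.28, adjusted p = 1.18e-09 by the same test), which was 1.42 ± 0.38 CPM in DMSO, 1.44 ± 0.441 in CAR, 11 ± 1.12 in JQ1 and 175 ± 4.47 in Combination.

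The other large values above the sum were those of SYT2 (3.25 ± 0.87), the acute phase gene SAA1 (2.86 ± 0.35), ITGA10 (2.44 ± 0.36), the liver cytochrome CYP2E1 (2.23 ± 0.55) and the growth factor FGF18 (2.20 ± 0.47). SYT2 had fallen under either agent and had only 0.176 ± 0.117 CPM in Combination. Its call was lost without Combination replicate 3 (adjusted p = 0.0804, log2 2.69) and its value was 4.85 without JQ1 replicate 1. FGF18 was 2.85 without CAR replicate 1. SAA1 and CYP2E1 are hepatocyte markers, and Combination replicate 1 held transcripts typical of liver. Without that library SAA1 and CYP2E1 were at 2.95 and 2. The largest values below the sum were those of AKR1B10 (-2.95 ± 1.16), CYP1B1 (-2.26 ± 0.10; 29 ± 1.64, 12 ± 1.34, 172 ± 6.26 and 14.8 ± 0.932 CPM), NAALAD2 (-2.05 ± 0.39), the transcription factor BATF3 (-2.05 ± 0.24), TESMIN (-1.95 ± 0.70) and THSD1 (-1.84 ± 0.19). The AKR1B10 call was lost without any of 9 single libraries (log2 -2.47 to -3.11), all but DMSO replicates 1 and 3 and Combination replicate 3, and without the last of these the value was -4.12. It was also lost with RLE scaling, the strict filter and the replicate number as a block (adjusted p = 0.0508, 0.0523 and 0.0629), and without both libraries that stood apart (0.0586). Its level in JQ1, 0.0734 ± 0.0289 CPM, lay under the floor of 3 counts per library. The TESMIN call was lost without JQ1 replicate 2 or 3 or Combination replicate 2 (log2 -1.95, -1.51 and -1.4), and with DESeq2 (adjusted p = 0.0557).

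Hypoxia and glycolysis genes were positive in 23 and negative in 1 of 29 (23 and 2 adjusted over the list alone, median 0.43, camera adjusted p = 1.85e-18), with BNIP3 at 1.02, P4HA1 at 0.82, LDHA at 0.75 and the glucose transporter SLC2A1 at -0.25, and this was the only list call of the 9 that held with an estimated correlation (adjusted p = 0.028). MYC and ribosome biogenesis genes were negative in 21 and positive in 0 of 33 (22 and 0 adjusted over the list alone, median -0.29, adjusted p = 6.99e-11; adjusted p = 0.0765 with an estimated correlation), with ODC1 at -0.94, POLR1B at -0.65, WDR43 at -0.63 and IMPDH2 at -0.54. Heat shock genes were negative in 14 and positive in 0 of 19 (14 and 1 adjusted over the list alone, median -0.34, adjusted p = 9.93e-08; adjusted p = 0.15 with an estimated correlation), with SERPINH1 at -0.67, FKBP4 at -0.57, HSPA8 at -0.52 and HSPD1 at -0.47. Cytosolic ribosomal protein mRNAs were negative in 24 and positive in 0 of 30 (25 and 0 adjusted over the list alone, median -0.24, adjusted p = 2.99e-06; adjusted p = 0.519 with an estimated correlation), with RPS18 at -0.40 and RPL30 at -0.31. Autophagy and lysosome genes were positive in 10 and negative in 2 of 22, also adjusted over the list alone (median 0.12, adjusted p = 0.00495; adjusted p = 0.15 with an estimated correlation), with MCOLN1 at 0.91, NEU1 at 0.67 and NPC1 at -0.34. Matrix proteolysis genes were positive in 12 and negative in 1 of 24 (12 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.0143; adjusted p = 0.15 with an estimated correlation), with PLAT at 0.80, CTSB at 0.42 and the urokinase receptor PLAUR at -0.84.

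The 3 remaining calls of the interaction were each lost when some single libraries were left out. G1/S genes were positive in 5 and negative in 10 of 30 (5 and 12 adjusted over the list alone, median -0.20, adjusted p = 0.0246; adjusted p = 0.52 with an estimated correlation), with RRM2 at -1.22, MCM7 at -0.60 and GINS1 at 0.69, and this call was lost without JQ1 replicate 1 (adjusted p = 0.0647), Combination replicate 1 (0.0635) or Combination replicate 2 (0.0949), with medians of -0.15, -0.14 and -0.11. G2/M genes were positive in 2 and negative in 10 of 29, also adjusted over the list alone (median -0.24, adjusted p = 0.0198; adjusted p = 0.656 with an estimated correlation), with CENPE at -0.97, and were lost without JQ1 replicate 1 (0.0965) or Combination replicate 2 (0.0891), with medians of -0.14 and -0.17. That call was also lost with length and GC correction (0.0728) and with fry (0.105). Homologous recombination genes were positive in 1 and negative in 7 of 18 (2 and 9 adjusted over the list alone, median -0.23, adjusted p = 0.033; adjusted p = 0.498 with an estimated correlation), with BRCA1 at -0.66, RBBP8 at -0.64 and FANCD2 at 0.44, and were lost without DMSO replicate 3 (0.172), JQ1 replicate 1 (0.0729), Combination replicate 1 (0.0886) or Combination replicate 2 (0.0572), though the medians were -0.19, -0.21, -0.21 and -0.22. That call was also lost with length and GC correction (0.13). The FANCD2 call was lost without JQ1 replicate 1 or 3 or Combination replicate 2 or 3 (log2 0.35, 0.4, 0.41 and 0.43). NRF2 targets went both ways (7 positive and 7 negative of 28, adjusted p = 0.0708; 0.0371 without DMSO replicate 2). Without DMSO replicate 3, nuclear OXPHOS subunits (median -0.15 against -0.08, adjusted p = 0.00225) and sterol and lipid synthesis (0.06 either way, adjusted p = 0.0157) were called as well. In all, 2536 genes were above and 2305 below the sum, 38.3% of those tested, and 276 and 126 of them by at least 2-fold. The share above was 52.4%, and 47.4% with total count scaling (2348 above and 2602 below) and 56.9% with upper-quartile scaling.

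**Figure D4:**
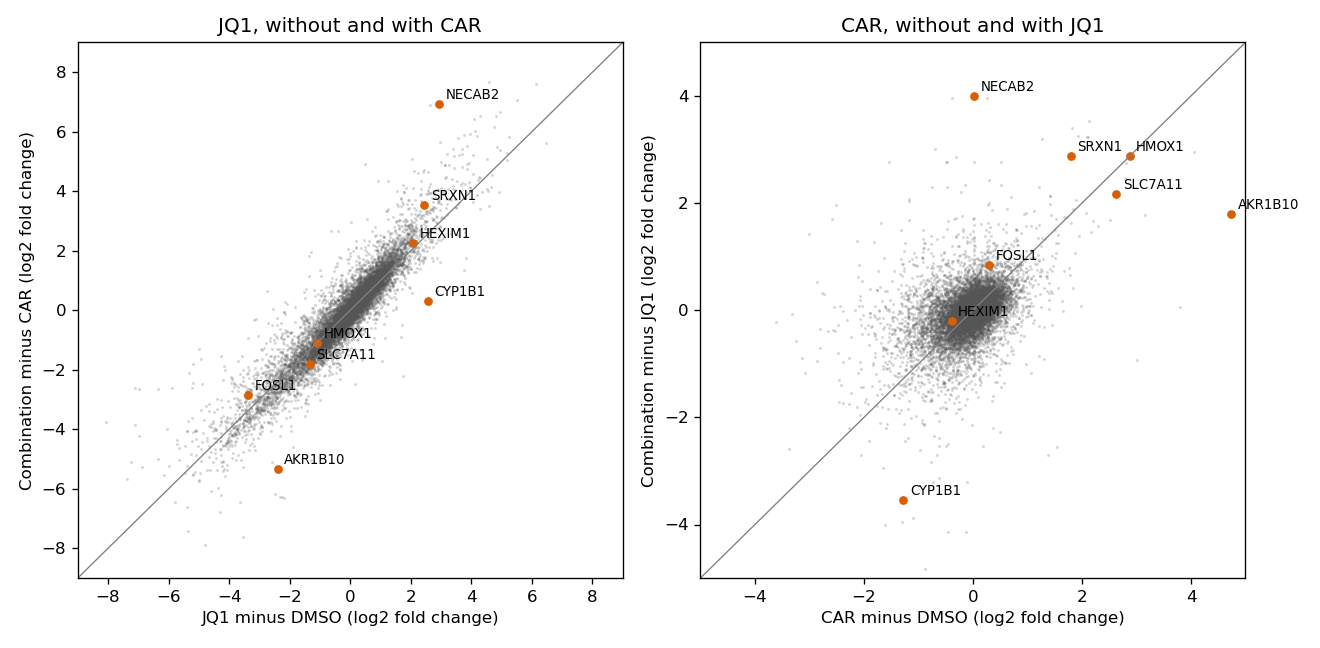
Log2 fold changes of each tested gene, with JQ1 minus DMSO (x axis) against Combination minus CAR (y axis) on the left and CAR minus DMSO (x axis) against Combination minus JQ1 (y axis) on the right; each point is a gene and the line marks equal values. Pearson's r across genes is 0.932 on the left and 0.431 on the right.

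The difference between the JQ1 effects with and without CAR equals, gene by gene, that between the CAR effects with and without JQ1, which is the interaction. The correlations that follow differ in the size of the effects as well, with a median absolute log2 change of 0.604 in JQ1 minus DMSO and 0.224 in CAR minus DMSO, and do not rank the agents. The 12645 genes are not independent replicates. Across them, log2 changes of JQ1 minus DMSO and Combination minus CAR had Pearson's r of 0.932 and Spearman's rho of 0.933. In both, 4692 genes were higher and 4757 lower (2225 and 2294 in independent lists). For CAR minus DMSO and Combination minus JQ1, r was 0.431 and rho 0.45. In both, 1748 genes were higher and 1875 lower (897.9 and 984.4 if independent). Total least squares slopes (1.117 and 0.995) compare spreads, not changes gene by gene. Neither pair shares a library. CAR minus DMSO and JQ1 minus DMSO share their DMSO libraries, which alone gave a mean r of 0.492 (0.424 to 0.536) in 20 simulations of unchanged groups. The observed r was -0.084 and rho -0.144, and the covariance was -0.0503 against 0.0137 in the simulations, a difference of -0.064. Both agents raised 1046 genes, where independent lists would share 1431, and both lowered 1452, against 1603. CAR raised and JQ1 lowered 1852 genes, against 1455 for independent lists, and CAR lowered and JQ1 raised 1853, against 1577. With 1 DMSO library as the control of one agent and the other 2 as that of the other, chosen after the data were seen, r of the mean log2 CPM differences was -0.11 to -0.075 over the 6 ways to do so, against -0.079 with all 3 for both.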

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

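The tests of the liver transcripts, of the hypoxia list and of a fixed share of OSGIN1 transcription, and the other groupings of the libraries, were chosen only after the results were seen; the interaction contrast was fixed beforehand. The test of transcription past gene ends was prompted by NECAB2, with its bounds written before its values were seen, and the NECAB2 tests took the place of 3 on ribosomal protein mRNAs whose results had been seen.

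Hepatocyte markers were seen in Combination replicate 1, although the cells are a breast cancer line. The 52 of the 62 listed markers that were too low to be tested held 2865 counts there and 14 to 41 in the other 11 libraries, and 57 of the 62 were highest in that library. A response to the drugs is argued against by the other Combination libraries, whose mean of 20.9 CPM for the summed markers lay within the 19.8 to 34.4 of all the libraries other than Combination replicate 1, which had 213. RNA from liver remains a candidate source, with ALB at 1429 counts and 231 genes counted in that library alone (at most 81 in any other), while the lists of pancreas, kidney, muscle, brain and blood cell markers were not raised there against the other Combination libraries. The cells themselves have at least 1 CPM (by the library total) of 6 of the markers in a DMSO library, and where the RNA entered was not tested.

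Hypoxia and glycolysis genes lay above the sum of the single-agent changes, with a median interaction of 0.43. RNA from liver is argued against as the cause by the median without Combination replicate 1, 0.475 with an SE over the members of 0.077. A trend with gene length or GC content is argued against by the median of 0.429 with corrected offsets, with the same SE. A response to the pair of agents and a difference in oxygen or cell density between the cultures cannot be told apart. Either may raise targets of the hypoxia factor HIF. Of 12 such targets outside glycolysis, 11 had a positive interaction call. They are members of the same list, so these calls repeat its result and decide nothing. No label gives oxygen or density.

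NECAB2 had an interaction of 3.98 and starts 2300 bp after the end of OSGIN1. Transcription that runs on from OSGIN1 at a fixed share is argued against by CAR alone, where NECAB2 changed by log2 0.02 ± 0.239 and OSGIN1 by 2.13 ± 0.0567. As a percentage of the CPM of OSGIN1, NECAB2 was 5.58 ± 1.05 in DMSO, 1.29 ± 0.326 in CAR, 22.3 ± 1.47 in JQ1 and 30.9 ± 1.77 in Combination (SD, n = 3). Transcription past gene ends in general under JQ1 stays open: the median JQ1 minus DMSO change of 250 low genes within 5 kb after the end of a gene at least 10 times higher lay 0.43 ± 0.19 (bootstrap SE) above that of 141 low genes before the start of such a gene (two-sided permutation test across genes, p = 0.0208 with 100000 resamples), between the bounds set for either answer. The same difference was 0.14, 0.41, 0.07, 0.48 and 0.08 in CAR minus DMSO, Combination minus DMSO, Combination minus JQ1, Combination minus CAR and the interaction (permutation p = 0.104, 0.0513, 0.193, 0.0592 and 0.411), so that a run-on that JQ1 raises and a start site of NECAB2 itself cannot be told apart.

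By the test of the interaction, 2536 genes lay above and 2305 below the sum of the single-agent changes. The genes with the largest differences were NECAB2 (3.98), SYT2 (3.25), SAA1 (2.86), ITGA10 (2.44), CYP2E1 (2.23) and FGF18 (2.2) above it, and AKR1B10 (-2.95), CYP1B1 (-2.26), NAALAD2 (-2.05), BATF3 (-2.05), TESMIN (-1.95) and THSD1 (-1.84) below it. The AKR1B10 call was lost with RLE scaling, the strict filter, the replicate number as a block, and without both Combination replicate 1 and DMSO replicate 3 (adjusted p = 0.0508, 0.0523, 0.0629 and 0.0586). CYP2E1 was at 2 without Combination replicate 1 and at 1.55 without DMSO replicate 3 as well. Lists that differed had medians of -0.29 (MYC and ribosome biogenesis), 0.17 (matrix proteolysis), -0.34 (heat shock), -0.2 (G1/S), -0.24 (G2/M), -0.23 (homologous recombination), 0.12 (autophagy and lysosome) and -0.24 (cytosolic ribosomal proteins), and all 8 of these calls were lost with an estimated correlation (adjusted p = 0.0765 to 0.656). Without both Combination replicate 1 and DMSO replicate 3 the G1/S, G2/M and homologous recombination calls were lost (adjusted p = 0.0975, 0.106 and 0.257 by camera), with medians of -0.10, -0.26 and -0.17.

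Among 100 groupings of the 12 libraries into 4 groups of 3, the real one included, 5 called as many interaction genes, with 4841 for the real grouping and 5932 for the highest other, and 67 called as many lists, with 9 for the real grouping and 18 for the highest other. These counts do not exclude chance, but the other groupings sort drug-treated libraries among their arms and hold drug effects, so they do not measure what chance gives without an interaction. The 4 other groupings with as many genes kept the 3 CAR libraries together, as did 2 groupings that called 0 genes by edgeR (631 and 636 at an unadjusted p under 0.05). For the 5 comparisons between groups, 10 splits are too few for a share under 0.05. The other splits mix both groups, so drug effects enter their spread and they do not measure chance. The number of splits with as many genes was 1 in each. In the contrasts' listed order, the real split called 7250, 10580, 10801, 6567 and 10800 genes and the highest other 0 (1173, 302, 212, 357 and 53 at an unadjusted p under 0.05) by edgeR's quasi-likelihood test. For lists the number was 5, 1, 2, 3 and 1, with 7, 13, 14, 6 and 16 lists for the real split and 8, 12, 14, 9 and 12 for the highest other.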

How the results depend on the processing

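Leaving out both Combination replicate 1 and DMSO replicate 3, offsets corrected for length and GC content, and separate DMSO libraries for CAR and JQ1, are tests chosen only after the results were seen; the other settings were planned. Over the single alternatives, the named genes reported here kept their direction and side of the threshold in 7933 cases, lost the call in 190 (115 of them with glmTreat), gained it in 10 and turned their sign in 33, and list calls were kept in 832 cases and lost in 67. The cause was not tested unless the setting itself gives it. A minimum fold of 1.5 (glmTreat) left, by construction, 184 higher and 431 lower genes in CAR minus DMSO, 2422 and 2996 in JQ1 minus DMSO, 2584 and 3215 in Combination minus DMSO, 181 and 299 in Combination minus JQ1, 2920 and 3271 in Combination minus CAR, and 165 and 89 in the interaction. Lists called with an estimated correlation numbered 2, 5, 9, 2, 5 and 1 in the same order. With fry, which does not compare a list with other genes, they numbered 21, 22, 23, 15, 24 and 16. CAR minus DMSO had 11 lists called without both doubted libraries. The correlation of the JQ1 effect with and without CAR was 0.956 with the strict filter, 0.935 with length and GC correction and 0.926 without both libraries; that of the CAR effect was 0.538, 0.447 and 0.419, and 0.45 with Spearman's rho; that between the agents was -0.142 with the strict filter, -0.048 without both libraries and -0.144 with Spearman's rho.

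Leaving out each library in turn gave 3135 to 3724 genes higher and 3386 to 4103 lower in CAR minus DMSO, 5125 to 5351 and 5191 to 5371 in JQ1 minus DMSO, 5246 to 5480 and 5299 to 5434 in Combination minus DMSO, 2906 to 3017 and 2893 to 3048 in Combination minus JQ1, 5253 to 5277 and 5325 to 5355 in Combination minus CAR, and 2256 to 3027 and 1982 to 2837 in the interaction. Lists called were 7 to 11, 13 to 13, 13 to 14, 6 to 6, 15 to 16 and 6 to 10. The correlations ran from 0.924 to 0.928 (JQ1 effect), 0.395 to 0.426 (CAR effect) and -0.102 to -0.048 (between the agents). CAR minus DMSO had its 11 lists without DMSO replicate 3, and the interaction its 6 without JQ1 replicate 1.

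Signs turned for genes near 0, and the cause was not tested. BRD2 in CAR minus DMSO was at -0.01 (RLE, DESeq2, length and GC correction, and without DMSO replicate 3, CAR replicate 1 or both doubted libraries), -0.02 (strict filter), -0.03 (upper quartile) and -0.06 (total count), and at most 0.01 with a library left out (CAR replicate 2). VIM in CAR minus DMSO was at -0.01 (upper quartile) and -0.04 (total count), and MYC in JQ1 minus DMSO at -0.01 and -0.07 in the same settings. MMP1 in JQ1 minus DMSO was at -0.09 without JQ1 replicate 1 and at 0.27 without DMSO replicate 1. In Combination minus DMSO it was at -0.05 (total count) and -0.03 (without both libraries), and in Combination minus JQ1 at -0.06 (total count, without Combination replicate 1 and without both) and -0.07 (without JQ1 replicate 2 or 3), against 0.25 without JQ1 replicate 1. HMOX1 in the interaction was at 0 (no filter, without CAR replicate 1 or Combination replicate 3), -0.02 (total count, without DMSO replicate 1 or CAR replicate 3), -0.03 (without Combination replicate 2), -0.05 (without JQ1 replicate 3; 0.03 without JQ1 replicate 2) and -0.12 (length and GC correction). COL6A1 in Combination minus DMSO was at -0.05 (total count) and -0.11 (length and GC correction), and IMPDH2 in Combination minus CAR at -0.01 (total count). Total count scaling moved the median of all genes by -0.119 in JQ1 minus DMSO, -0.207 in Combination minus DMSO and -0.142 in Combination minus CAR, and gave 41 opposite calls in Combination minus DMSO.

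Length and GC correction gave 6, 14 and 29 opposite calls in JQ1 minus DMSO, Combination minus DMSO and Combination minus CAR. For the ribosomal protein list in CAR minus DMSO, 3 explanations were tested and each left the median above 0: it was 0.268, and 0.216 with length and GC correction, 0.348 without DMSO replicate 3, 0.203 with total count scaling and 0.346 without both doubted libraries. The replicate numbers did not pair the libraries. Deviations of same-numbered libraries had correlations of -0.045 to 0.056 over 18 pairs, and 2 of 12 libraries correlated best with their own number. With the replicate number as a block, 7221, 10551, 10786, 6518, 10786 and 4785 genes were called in the 6 contrasts, and the epithelial list in JQ1 minus DMSO passed at an adjusted p = 0.0468 by camera; the block changed no other list call. At 17449715 counts and more per library, depth limits mainly genes near the floor of 0.152 to 0.172 CPM, such as CDH1 and MMP9. The correlation of the CAR and JQ1 effects on mean log2 CPM moved from -0.079 to -0.098 with DMSO replicate 1 for CAR and the others for JQ1, to -0.106 with DMSO replicate 2 for JQ1 alone, to -0.101 with DMSO replicate 3 for JQ1 alone and to -0.11 with DMSO replicate 3 for CAR alone.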

Other observations

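The gene lists and tests in this part were chosen only after the results were seen. Ferritin heavy chain (FTH1) rose from 1780 ± 167 CPM in DMSO to 6820 ± 74.1 in CAR (3.83-fold), 4750 ± 110 in JQ1 (2.67-fold) and 12400 ± 676 in Combination (6.95-fold; SD, n = 3). The transferrin receptor TFRC, which imports iron, rose under CAR and fell under JQ1, from 489 CPM to 885 in CAR (log2 0.86) and 316 in JQ1 (-0.63). The iron exporter SLC40A1 was 19.5 CPM in DMSO, 8.99 in CAR (log2 -1.12) and 47.9 in JQ1 (1.29). Of 14 iron genes, 9 were higher and 4 lower in CAR, 8 and 5 in JQ1 and 9 and 4 in Combination than in DMSO, where 57.3%, 83.7% and 85.4% of all tested genes were called.

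Among targets of the aryl hydrocarbon receptor, CYP1A1 was 5.64 ± 0.572 CPM in DMSO, 2.37 ± 0.442 in CAR, 22 ± 1.51 in JQ1 and 4.02 ± 0.166 in Combination, and CYP1B1 followed the same order with 172 ± 6.26 CPM in JQ1. AHRR, the repressor of that receptor, was highest in Combination (1.58, 0.691, 5.11 and 9.69 CPM), with an interaction of 2.10. Of the 8 targets tested, 6 rose and 2 fell in JQ1, and 2 rose and 3 fell in CAR. The ID factors, which block helix-loop-helix proteins, rose in 4 of 4 cases under JQ1 with a median of 4.44, and ID1 went from 22.9 ± 5.65 to 474 ± 16.1 CPM (20.6-fold). Of 12 genes of class I antigen presentation, 2 rose and 9 fell in CAR, and 5 rose and 4 fell in JQ1: B2M was 751 ± 51.6, 580 ± 10.8, 1310 ± 19.4 and 1080 ± 17.4 CPM, whereas the immunoproteasome subunit PSMB8 fell under JQ1 (log2 -1.74). Of 5 metallothionein genes tested, 0 rose and 3 fell in CAR, and 2 rose and 2 fell in JQ1, in edgeR's quasi-likelihood test. The hypoxia list's rise from JQ1 to Combination, seen above, was 15 of 17 glycolytic enzymes (median 0.60) and 12 of 12 HIF targets outside glycolysis (0.66).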
